A study of Sus scrofa with 21 samples.

How the data were processed

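Total RNA was sequenced from the hearts of 21 pigs, 1 library per pig. Per the labels' protocols, the myocardial infarction (MI) pigs had a permanent tie around the left descending coronary artery, and per the labels the injury was on postnatal day 1, and RNA came from the border zone of the infarct or from the matching region of control hearts. The sample titles call the control pigs naive, while the protocol describes age-matched pigs that had the whole operation except the ligation. Which of the descriptions applies is not settled by the sources used here, and the control groups are called naive below. Sex, litter, library batch and sequencing date are not given in the sources used here. The pig numbers in the titles matched the columns of the deposited table for each of the 21 samples.

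The authors deposited raw read counts per Ensembl gene, 25880 genes by 21 libraries, all whole numbers. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR 2.5.2 to the Sscrofa11.1 genome, counted with HTSeq 0.6.1 and analysed with DESeq2. The annotation release, the strand setting and the versions of Trim Galore and DESeq2 are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be assigned, and reads shared by near-identical gene copies could have been split or dropped. A symbol was present in the deposited table for 17947 genes and was added by gene ID from a reference table of names for 807 more, while 7126 genes had none. Of all IDs, 14857 were in that reference table. Where a symbol was carried by several IDs (1952 additional IDs), the ID with the highest total count was used for list members and markers.

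Total counts per library ranged from 37002909 to 95559841. The 13 mitochondrially encoded genes took 15.8% to 34.6% of the counts, and COX1 was the most abundant gene of every library. Pooled over genes, where abundant genes weigh most, counts of 2 libraries of the same group differed by 54.3 to 964 times the variance expected from counting alone (chi-square per degree of freedom over 18 pairs).

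Genes were kept with filterByExpr of edgeR 4.0.16 on the 8 groups (15359 genes, 13709 of them with a symbol). Libraries were scaled by trimmed mean of M values (TMM), and a negative binomial model with 1 mean per group was fitted to all 21 libraries (glmQLFit with robust = TRUE, 13 residual degrees of freedom, common dispersion 0.139, biological coefficient of variation 0.37). Each comparison was a contrast tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the 15359 genes. A gene is called when its adjusted p is under 0.05. The 9 comparisons were MI against naive hearts on days 7, 14 and 28, the change of the MI effect from day 7 to day 14 and from day 7 to day 28 (interaction contrasts), and naive hearts on day 3 against day 1, day 7 against day 1, day 14 against day 7 and day 28 against day 7. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are given as CPM (edgeR's cpm with TMM-scaled library sizes), as mean ± SD over pigs or, for some groups of 2, per library. The analysis used R 4.3.3, and figures were drawn with matplotlib 3.10.9.

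The comparisons, tests, gene lists, the rule for naming genes and all settings but the last 2 below were chosen before the data were examined. The 31 lists cover the cell cycle (DNA replication and S phase, G2 and mitosis, G1 cyclins and CDK inhibitors), growth (cardiac growth and regeneration regulators, imprinted fetal growth genes, YAP and TEAD targets), cardiomyocytes (contractile apparatus and calcium handling, fetal and stress genes), matrix, metabolism (fatty acid oxidation, nuclear and mitochondrially encoded oxidative phosphorylation subunits, glycolysis, hypoxia), responses (interferon, inflammatory, immediate early, heat shock) and markers of other tissues (fibroblasts, macrophages, lymphocytes, neutrophils, endothelium, smooth muscle, epicardium, adipocytes, erythroid cells, Schwann cells, atria, skeletal muscle) and sex-linked genes. Of the 9 sex-linked genes, 5 were in the table and 0 passed the filter, so that list was not tested and 30 were. Marker lists are lists of genes: no cells were classified. For each list, calls were counted with adjustment over all genes and adjusted over the list alone, and the list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Camera with a correlation estimated for each list and fry were run beside it. Camera with the preset correlation called 7 to 14 lists per comparison, and 0 of these calls in any comparison held with an estimated correlation, so list results are worded as positions, not as rises or falls.

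Genes are named by 3 rules: from each list up to 4 called members with the smallest adjusted p, or, where none was called, up to 2 with the highest mean expression; the 5 largest rises and 5 largest falls among called genes with a symbol, a mean log2 CPM above 1 and no overlap between the groups; and 12 marker genes, called or not. MYH6 and IGF2, among the markers, were not in the table by symbol, and TNNI3 had 0 counts in every library. These rules set which genes can be named, and many of the genes that they pick are not reported here. Genes outside these rules are named as chosen after their values were seen.

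The procedure was tested on simulated data: counts for the 15359 genes with the means, dispersions and library sizes of the real samples, and 200 genes changed 2-fold or 4-fold (100 each). The 27 oxidative phosphorylation subunits were also lowered 2-fold. Genes were drawn independently, with the same spread in every library, while limma voom gave the real libraries weights of 0.32 to 4.83. The false calls below are therefore those of the simulated data only. In the simulated comparison of MI with naive hearts on day 28, edgeR called 20% of the 2-fold and 73% of the 4-fold changes. On day 7 it called 34% and 88%, and for the change in MI effect from day 7 to day 28 it called 4% and 44%. Of the calls, 2, 9 and 3 were false in these comparisons by edgeR, against 31, 35 and 25 by DESeq2's Wald test (1.42.0).

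Alternatives planned for every comparison were DESeq2 size factors in place of TMM, DESeq2's Wald test, no count filter, a fit to the compared groups alone, limma voom with sample weights, removal of 5 haemoglobin and 13 mitochondrial genes before scaling, and leaving out each library of the comparison in turn. After the data were seen, a term for a set of 4 libraries that differ in a few features, and removal of those 4 libraries, were added. Camera with the preset correlation was rerun under all of these but DESeq2's Wald test and voom, 10 to 18 alternatives per comparison, which the report calls alternatives of the fit. Other splits of the samples were counted for the comparisons of groups of 3. Pseudocount alternatives were not run because the values are counts. Dixon's test for a sample far from its group was not applied. The largest group has 3 samples, too few for the test to have much power.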

Results

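RNA was measured in heart tissue of 21 newborn to 4-week-old pigs, each library from a separate pig. The 8 groups were naive hearts on postnatal days 1 (n = 2), 3 (n = 2), 7 (n = 3), 14 (n = 3) and 28 (n = 3), and hearts with a myocardial infarction (MI) made on day 1 and collected on day 7 (n = 3), 14 (n = 3) and 28 (n = 2). MI tissue came from the border zone next to the ischaemic area. Total counts per library were 75071994 to 92831231 in the MI day 7 group and 37002909 to 48321350 in the naive day 7 group. They were 57822106 to 95559841 in MI and 51713747 to 68247768 in naive hearts on day 14, and 49764677 to 78662965 in MI and 51626718 to 74912650 in naive hearts on day 28. The naive groups of days 1 and 3 had 51694314 to 59132559 and 59223803 to 61725346 counts. Over all tested genes, pairs of libraries of the same group correlated at a median Pearson r of 0.966 (18 pairs) and pairs from different groups at 0.962 (192 pairs), both across genes. The pair with the lowest r within a group, 0.913, was the MI day 28 pair.

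Among the libraries, 4 differed from the other 17 in a few features: MI day 28 replicate 2, MI day 7 replicate 3, naive day 14 replicate 3 and naive day 28 replicate 2. They had 5.32 to 11.6 CPM of ENSSSCG00000035520, against 3.18e+03 to 7.21e+03 CPM in the others. They had 33.8 to 77.1 CPM of ENSSSCG00000018073 and 27.5 to 56.8 CPM of ENSSSCG00000018072, against at most 0.135 and 0.116 CPM. ND1, a mitochondrially encoded gene, took 0.88% to 1.58% of their counts, against 0.25% to 0.57% in the others. Together, the mitochondrially encoded genes took 19.2% to 30.9% in these 4 libraries and 15.8% to 34.6% in the others. The labels name no library batch, and this second set holds 1 library in each of 4 groups.

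Compared with naive hearts, MI hearts on day 28 had higher inflammatory and immediate early lists, a macrophage list that was high in 1 of the 2 MI libraries, and lower lists for contraction, fatty acid oxidation and respiration. None of these lists was called with an estimated correlation. This comparison asks what the border zone expresses 4 weeks after an infarct made at birth. The chemokine CXCL2 (ENSSSCG00000008959), which draws neutrophils, rose by a log2 fold change of 3.57 (SE 0.54, edgeR adjusted p = 0.00702), from 4.65 ± 0.391 CPM in naive hearts (n = 3) to 55.1 and 55.8 CPM in the MI libraries. NDUFS1 (ENSSSCG00000016127), the largest subunit of respiratory complex I, fell from 443 ± 18.3 CPM to 182 ± 2.28 CPM (n = 2), a log2 fold change of -1.29 (SE 0.31, adjusted p = 0.0294). CASQ2 (ENSSSCG00000006745), the calcium store protein of the sarcoplasmic reticulum, fell from 505 ± 29.5 to 156 ± 6.72 CPM (-1.69, SE 0.46, adjusted p = 0.0392). CXCL2 stayed called when either MI library was left out. NDUFS1 and CASQ2 each lost the call in at least 1 of these fits, which keep a single MI library. In all, edgeR called 1053 of 15359 genes, 687 higher and 366 lower in MI. The groups did not overlap for 946 of the calls (89.8%), against 5806 of all tested genes (37.8%) and the 20% that chance gives.

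The number of day 28 calls depended on the libraries and on the test. It was 17 without naive day 28 replicate 3, 169 and 314 without the other naive libraries, 1162 without MI day 28 replicate 1 and 863 without replicate 2, with 535 and 354 of the 1053 genes among the last 2 counts. DESeq2 called 2205 genes, voom with sample weights 46, and a fit to the 5 libraries alone 2. The reported fit shares its spread over all 8 groups, while the MI day 28 pair had the lowest r within a group (0.913). With a term for the second set of libraries the count was 646. The balance of directions moved too, with 1034 higher and 128 lower without MI replicate 1, 539 and 324 without replicate 2, 44 and 2 by voom, and 550 and 450 without the 4 libraries of the second set.

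**Figure D1:**
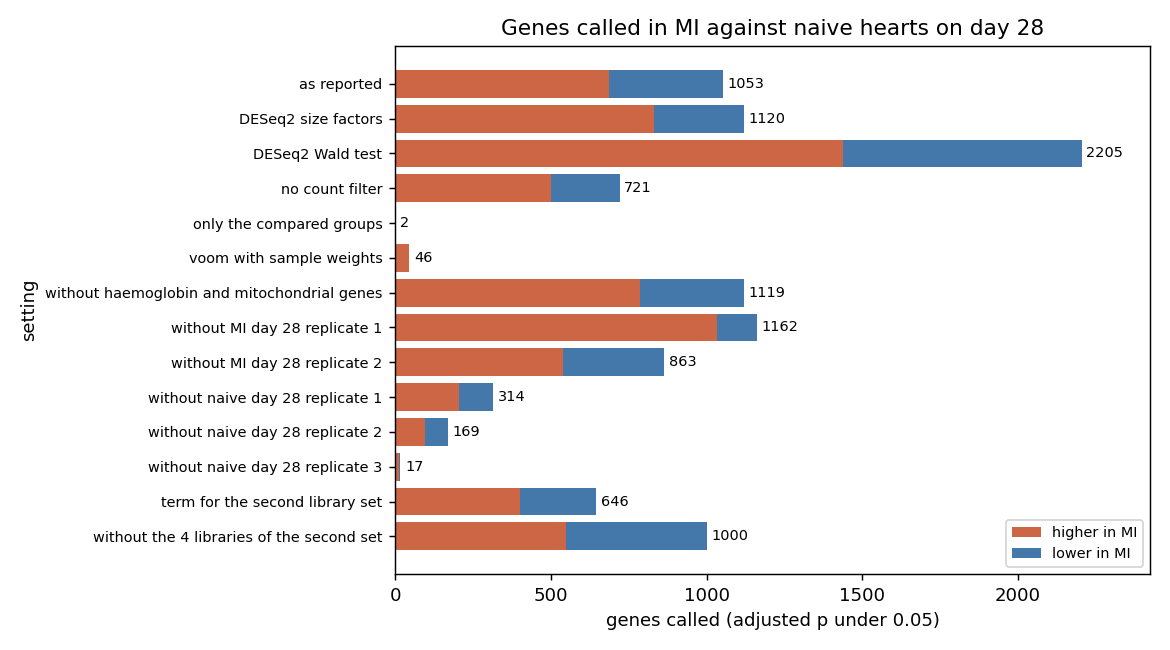
Number of genes called in MI against naive hearts on day 28 (horizontal axis, adjusted p under 0.05) for each setting (vertical axis), with genes higher and lower in MI stacked. The count was 1053 as reported and ranged from 2 to 2205.

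Macrophage and monocyte markers lay higher in MI hearts on day 28. Of 21 tested, 13 were called higher (18 adjusted over the list alone), with a median log2 fold change of 2.93 (camera adjusted p = 9.84e-08, and adjusted p = 0.513 with an estimated correlation). CD14, a receptor for bacterial lipopolysaccharide, rose by 2.53 (SE 0.51, adjusted p = 0.018) from 7.15 ± 2.46 CPM to 22.3 and 60 CPM. TREM2, a lipid receptor of tissue macrophages, rose by 3.41 (SE 0.72, adjusted p = 0.0195), and its adaptor TYROBP rose by 3.06 (SE 0.66, adjusted p = 0.0215). CD68, a lysosomal protein of macrophages, rose by 3.28 (SE 0.77, adjusted p = 0.0266), with 7.37 CPM in MI replicate 1 and 98.3 CPM in replicate 2 against 5.44 ± 3.34 CPM in naive hearts. The mean level of the list was 3.39 log2 CPM in MI replicate 1, 6.33 in replicate 2, and 3.38, 3.11 and 1.38 in the naive libraries. Without MI replicate 2, the list median was 0.44 (camera adjusted p = 0.0996) and CD68 stood at 0.47, with an adjusted p of 0.708.

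The inflammatory list lay higher in both MI libraries, at 1.87 and 3.36 log2 CPM against 0.72, 0.86 and -0.17 in the naive ones. Of 17 tested cytokines and adhesion molecules, 8 were called higher on day 28 (14 adjusted over the list alone), with a median of 2.26 (camera adjusted p = 1.13e-07, and 0.335 with an estimated correlation). SOCS3, which dampens cytokine signalling, rose by 3.19 (SE 0.61, adjusted p = 0.0142). PTGS2, the inducible enzyme of prostaglandin synthesis, rose by 3.73 (SE 0.79, adjusted p = 0.0204), and ICAM1, which lets leukocytes adhere to vessels, rose by 1.7 (SE 0.32, adjusted p = 0.0141). Immediate early genes, switched on within minutes of a stimulus, lay higher too: 5 of 13 were called (7 adjusted over the list alone), with a median of 1.87 (camera adjusted p = 5.64e-06, and 0.154 with an estimated correlation). IER2 rose by 1.87 (SE 0.3, adjusted p = 0.00702), the MAP kinase phosphatase DUSP1 by 2.06 (SE 0.4, adjusted p = 0.0159), the antiproliferative gene BTG2 by 1.8 (SE 0.42, adjusted p = 0.0266), and the transcription factor FOS from 13.8 ± 16.6 to 162 ± 35.3 CPM (3.56, SE 0.89, adjusted p = 0.0312). The camera calls of both lists held in every alternative of the fit, and fry called both (adjusted p = 0.00858 and 0.00101). CXCL2, ICAM1, SOCS3, PTGS2, IER2 and DUSP1 stayed called when either MI library was left out. Without naive replicate 3, of these 6 genes CXCL2 alone stayed called (adjusted p = 0.0451).

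**Figure D2:**
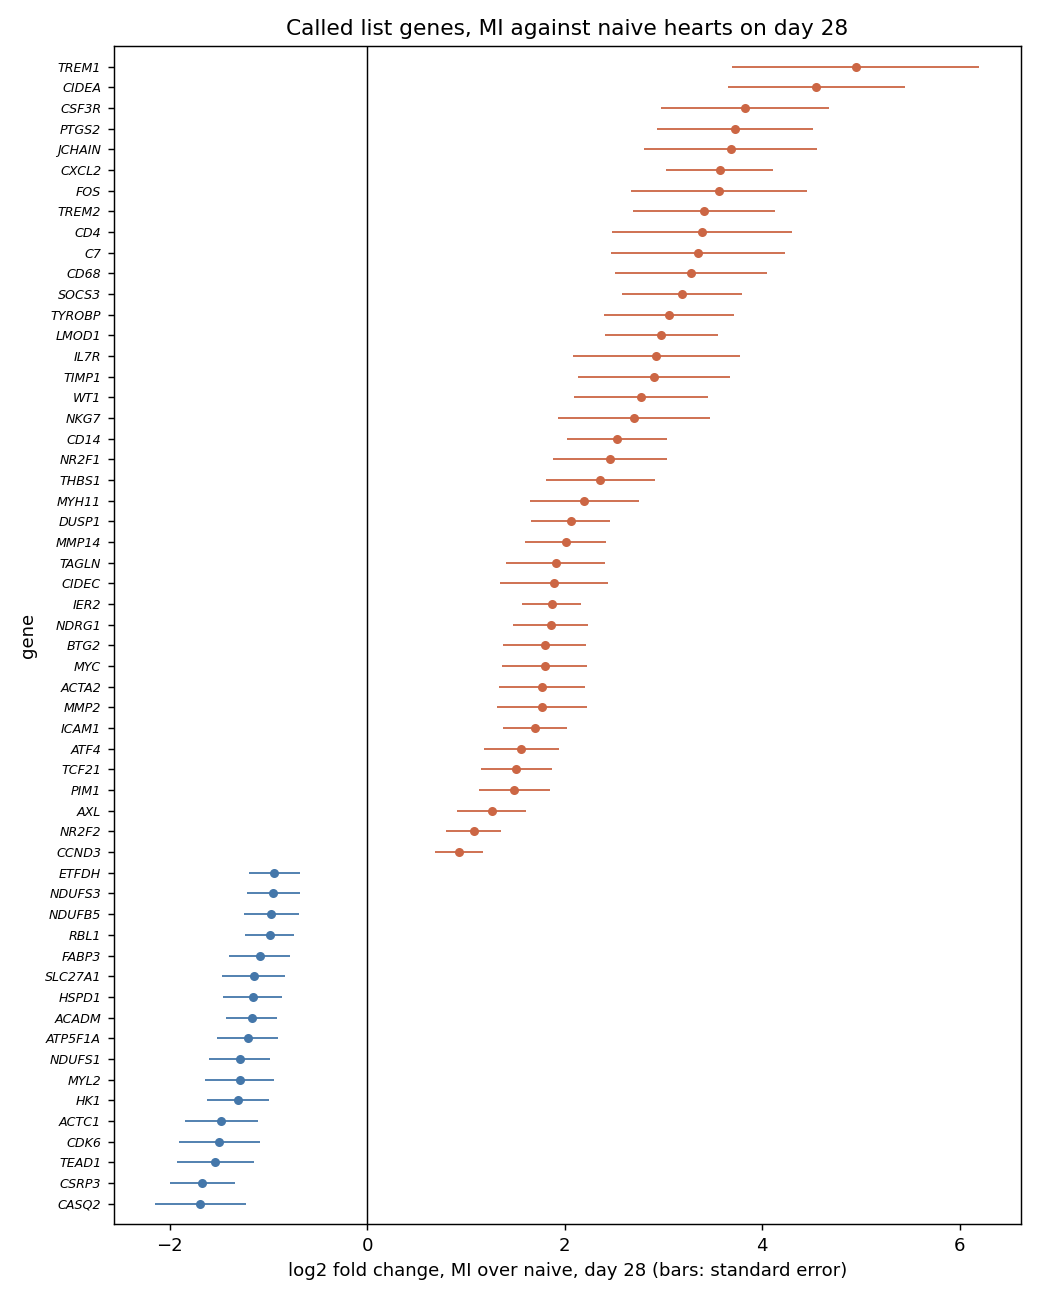
Log2 fold change of MI over naive hearts on day 28 (horizontal axis) for 56 called genes named from the gene lists (vertical axis), with the standard error as bars; ADIPOQ, at 10.55, and the fetal and stress list are left off. Of these, 39 were higher, from CCND3 at 0.93 to TREM1 at 4.95, and 17 were lower, from ETFDH at -0.94 to CASQ2 at -1.69.

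Lymphocyte markers were high mostly in MI replicate 2. The neutrophil list lay higher in both MI libraries, but at low levels, and its called member CSF3R was clearly raised in replicate 2 alone. The neutrophil levels were -0.95 and 1.3 log2 CPM, against -3.1, -3.25 and -2.94 in naive hearts. The neutrophil list had 2 of 8 genes called (6 adjusted over the list alone), with a median of 4.39 (camera adjusted p = 0.00108, and 0.513 with an estimated correlation; fry adjusted p = 0.0452). CSF3R, the receptor for granulocyte growth factor, rose by 3.83 (SE 0.85, adjusted p = 0.0223), with 0.824 and 17.4 CPM in the MI libraries against 0.638 ± 0.177 CPM. TREM1, an amplifier of inflammation, rose by 4.95 (SE 1.25, adjusted p = 0.0339). Lymphocyte markers had 4 of 20 called (5 adjusted over the list alone) and a median of 1.69 (camera adjusted p = 0.00108, and 0.701 with an estimated correlation). JCHAIN, which joins antibody units, was at 2.63 and 67.6 CPM against 2.73 ± 1.39 CPM, and the T cell receptor partner CD4 at 1.1 and 43.9 CPM against 2.14 ± 0.624 CPM. Their log2 fold changes were 3.68 (SE 0.88, adjusted p = 0.0288) and 3.39 (SE 0.91, adjusted p = 0.0381). NKG7, of cytotoxic cells, rose by 2.7 (SE 0.77) and the cytokine receptor IL7R by 2.93 (SE 0.85), with adjusted p of 0.0456 and 0.0479. Without MI replicate 2, JCHAIN and CD4 turned to -0.03 and -0.93, the lymphocyte list median to -0.66 and the neutrophil list lost its camera call (median 3.06, adjusted p = 0.126).

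Matrix, fibroblast and epicardial genes were higher in the MI library that also carried the macrophage markers. Of 32 matrix genes 4 rose (8 adjusted over the list alone), with a list median of 1.06 (camera adjusted p = 0.0202, and 0.715 with an estimated correlation). The membrane protease MMP14 rose by 2.01 (SE 0.41, adjusted p = 0.0188) and the gelatinase MMP2 by 1.77 (SE 0.46, adjusted p = 0.0351). TIMP1, an inhibitor of such proteases, rose by 2.9 (SE 0.77, adjusted p = 0.0374) from 19 ± 3.99 CPM to 101 and 184 CPM. THBS1, a matrix protein released on injury, rose by 2.36 (SE 0.55, adjusted p = 0.0269), at 1.15e+03 and 153 CPM against 127 ± 17.4 CPM, and stood at 0.29 without MI replicate 1. COL1A1, the main scar collagen, was not called (1.72, SE 0.86, adjusted p = 0.209), at 400 and 6.43e+03 CPM against 1.03e+03 ± 352 CPM, nor was POSTN, made by activated fibroblasts (2.09, SE 1.03, adjusted p = 0.204). Of 14 fibroblast markers 2 were called (2 adjusted over the list alone): the transcription factor TCF21 (1.51, SE 0.36, adjusted p = 0.0289) and the complement component C7 (3.35, SE 0.88, adjusted p = 0.0362) rose. Camera did not call the list (median 0.82, adjusted p = 0.267). WT1, a transcription factor of the epicardium, rose by 2.77 (SE 0.68, adjusted p = 0.0308), the only call among 8 epicardial markers (3 adjusted over the list alone; median 1.45, camera adjusted p = 0.0224, and 0.677 with an estimated correlation). Without MI replicate 2, the matrix median was -0.26, the epicardial median 0.61, and neither list was called.

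Smooth muscle and fat markers that were called were high mostly in the other MI library, replicate 1, TAGLN excepted. LMOD1 (2.98, SE 0.57, adjusted p = 0.0147), ACTA2 (1.77, SE 0.44, adjusted p = 0.0308), MYH11 (2.2, SE 0.55, adjusted p = 0.0311) and TAGLN (1.91, SE 0.5, adjusted p = 0.035), all parts of the smooth muscle contractile apparatus, rose (4 of 12 markers, and 4 adjusted over the list alone). Over these smooth muscle and pericyte markers the median was -0.1 and the mean 0.56, of opposite sign, and camera did not call the list (adjusted p = 0.289). Of 6 adipocyte markers, 3 rose (5 adjusted over the list alone), with a median of 4.49 (camera adjusted p = 0.00356, and 0.513 with an estimated correlation). The fat hormone ADIPOQ was at 116 CPM in MI replicate 1 and 0.0339 CPM in replicate 2, against 0.0309 ± 0.0397 CPM in naive hearts. Its fitted log2 fold change of 10.55 (SE 2.63, adjusted p = 0.0311) rests on 1 library, as do those of the lipid droplet proteins CIDEA (4.55, SE 0.9, adjusted p = 0.0159) and, in part, CIDEC (1.89, SE 0.55, adjusted p = 0.0498). Without MI replicate 1, the adipocyte median was 0.22, ADIPOQ stood at -0.02, and ACTA2 and MYH11 at 0.52 and 0.75, none of them called.

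The contractile list of the cardiomyocyte lay lower in MI hearts on day 28. Of 22 contractile and calcium handling genes 4 fell (7 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.8e-06, and 0.335 with an estimated correlation). CSRP3, a stretch sensor of the Z disc, fell from 616 ± 107 to 194 ± 79.9 CPM (-1.67, SE 0.33, adjusted p = 0.017). The sarcomere proteins ACTC1 and MYL2 fell by 1.48 (SE 0.37) and 1.29 (SE 0.35), with adjusted p of 0.0315 and 0.0409. CSRP3, ACTC1 and MYL2, like CASQ2, each lost the call when 1 or the other MI library was left out. MYH7, the slow myosin heavy chain, was not called (-0.88, SE 0.35, adjusted p = 0.124). Of the 14 fetal and stress genes, the chaperone CRYAB fell (-1.22, SE 0.31, adjusted p = 0.0324) and the list was not called (median -0.6, adjusted p = 0.193; 1 higher and 2 lower adjusted over the list alone). NPPA and NPPB, hormones of the strained heart, were not called (adjusted p = 0.465 and 0.844). Without the 4 libraries of the second set, the contractile list had a median of -0.39 and lost its camera call (adjusted p = 0.0945).

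The lists of nuclear genes for mitochondrial energy lay lower on day 28. Of 27 subunits of oxidative phosphorylation 4 fell (15 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 4.2e-08, and 0.538 with an estimated correlation). Besides NDUFS1, these were the ATP synthase subunit ATP5F1A (-1.21, SE 0.31, adjusted p = 0.0347) and the complex I subunits NDUFB5 (-0.97, SE 0.28, adjusted p = 0.0456) and NDUFS3 (-0.95, SE 0.27, adjusted p = 0.0479). Of 25 genes of fatty acid uptake and oxidation 4 fell (16 adjusted over the list alone, which also called 1 higher), with a median of -0.81 (camera adjusted p = 3.26e-06, and 0.513 with an estimated correlation). ACADM, which oxidises medium-chain fatty acids, fell from 389 ± 44.1 to 173 ± 21.8 CPM (-1.17, SE 0.26, adjusted p = 0.0229). The transporter SLC27A1 (-1.15, SE 0.32), the electron carrier ETFDH (-0.94, SE 0.26) and the fatty acid carrier FABP3 (-1.09, SE 0.31) fell, with adjusted p of 0.0417, 0.042 and 0.0456. Each of the subunits and fatty acid genes named here lost the call when 1 or the other MI library was left out. HK1, which phosphorylates glucose, fell by 1.31 (SE 0.31, adjusted p = 0.0266). It was the only call among 20 glycolysis genes (3 adjusted over the list alone, list median -0.32, camera adjusted p = 0.0784). The 13 mitochondrially encoded genes had a median of 0.3 and 0 calls by edgeR (camera adjusted p = 0.476). The camera calls of the nuclear oxidative phosphorylation and fatty acid lists held in every alternative of the fit, and fry called the contractile and fatty acid lists (adjusted p = 0.00927 and 0.0435).

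Cell cycle genes, the subject of the study's title, lay lower in MI hearts on day 28 as lists, with 0 calls by edgeR in the S phase and mitosis lists. The G2 and mitosis list (33 genes) had a median of -1.44 (camera adjusted p = 8.61e-05) and the S phase list (27 genes) one of -0.97 (camera adjusted p = 0.00439), each with adjusted p = 0.701 with an estimated correlation. MKI67, a marker of cycling cells, was at 19.8 and 145 CPM in the MI libraries and 34 ± 20.1 CPM in naive hearts (1.28, SE 0.88, adjusted p = 0.362), and the mitotic cyclin CCNB1 stood at -2.19 (SE 1.08, adjusted p = 0.2). Without MI replicate 1, the G2 and mitosis median was -0.82 (camera adjusted p = 0.0937) and the S phase median -0.49 (0.106). Among 17 G1 regulators, the growth factor target MYC (1.8, SE 0.43, adjusted p = 0.0279) and the cyclin CCND3 (0.93, SE 0.24, adjusted p = 0.035) rose, while the kinase CDK6 (-1.5, SE 0.41, adjusted p = 0.042) and the pocket protein RBL1 (-0.99, SE 0.25, adjusted p = 0.0347) fell. In all, 2 of the 17 rose and 3 fell (3 and 3 adjusted over the list alone). TEAD1, the DNA-binding partner of YAP, fell from 64.2 ± 2.11 to 22.1 ± 1.31 CPM (-1.54, SE 0.39, adjusted p = 0.0329). The survival kinase PIM1 rose (1.49, SE 0.36, adjusted p = 0.0289), and so did the receptor AXL, a YAP target (1.26, SE 0.35, adjusted p = 0.0424). The AXL rise was in MI replicate 2 alone, at 144 CPM against 47.1 CPM in replicate 1 and 50.7, 43.7 and 25.3 CPM in naive hearts. None of the lists of G1 regulators (median 0.28, camera adjusted p = 0.825), growth and regeneration regulators (-0.24, 0.25; 2 higher and 2 lower adjusted over the list alone), YAP and TEAD targets (-0.23, 0.481; 2 higher) and imprinted genes (-0.16, 0.491) was called.

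By the naming rule, the largest rises on day 28 were in C3, C4A, CFP, GFPT2 and LYZ. C3, the central complement protein, rose by 5.44 (SE 1.3, adjusted p = 0.0288), at 163 and 2.74e+03 CPM against 33.3 ± 13.5 CPM, and C4A by 5.14 (SE 1.28, adjusted p = 0.0311). Properdin (CFP) rose by 4.72 (SE 0.83, adjusted p = 0.012) and lysozyme (LYZ) by 4.45 (SE 0.88, adjusted p = 0.0167). GFPT2, which feeds the synthesis of hexosamines, rose by 4.66 (SE 0.67, adjusted p = 0.00702), at 255 and 105 CPM against 7.12 ± 2.76 CPM. The largest falls were in TNFRSF9 (-3.79, SE 1.05), the corepressor HR (-3.42, SE 0.54), the heart growth factor FGF16 (-3.24, SE 0.57), the G protein subunit GNB3 (-3.03, SE 0.87) and the basement membrane collagen COL4A5 (-2.78, SE 0.69), with adjusted p of 0.0426, 0.00702, 0.012, 0.0476 and 0.0308. Without MI replicate 2, C3, C4A, CFP and LYZ stood at 2.32, 2.37, 1.45 and 2.62, with adjusted p of 0.268, 0.267, 0.178 and 0.0888. TNFRSF9 was at -2.3 (adjusted p = 0.158) without naive replicate 3 and GNB3 at -1.58 (0.169) without naive replicate 2. Of the 69 called genes that the naming rules pick in this comparison, 9 stayed called when either MI library was left out, and CXCL2, GFPT2 and HR stayed called whichever of the 5 libraries was left out.

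The other lists on day 28 were not called by camera. NDRG1, induced by low oxygen, rose by 1.86 (SE 0.38, adjusted p = 0.018), the only call among 12 hypoxia genes (2 adjusted over the list alone), at a list median of 0.5 (camera adjusted p = 0.198). The stress factor ATF4 rose (1.56, SE 0.38, adjusted p = 0.0291, but 0.17 without MI replicate 1) and the mitochondrial chaperone HSPD1 fell (-1.16, SE 0.3, adjusted p = 0.0329) within a heat shock list of 14 genes at -0.45 (0.344; 1 higher and 1 lower adjusted over the list alone). The atrial transcription factors NR2F1 (2.46, SE 0.58, adjusted p = 0.0268) and NR2F2 (1.08, SE 0.28, adjusted p = 0.0362) rose, with the list of 7 atrial markers at -0.39 (0.587; 2 adjusted over the list alone). Endothelial markers had a median of 0.25 (0.193), with PECAM1 at 0.05 and VWF at 0.9 (SE 0.36, adjusted p = 0.122). The medians were 0.21 for interferon response (0.301), 0.5 for erythroid genes (0.484), 1.09 for Schwann cell markers (0.69) and 1.8 for the 3 tested skeletal muscle markers (0.491), with 0 calls by edgeR among their members.

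Compared with naive hearts, MI hearts on day 7 had lower cell cycle and respiratory lists, and no gene passed the test. This comparison asks what differs within 1 week of the injury, when cell cycle activity in the injured newborn heart was the study's subject. All 27 S phase genes lay lower, with a median of -1.06 (camera adjusted p = 7.34e-12), as did all 33 G2 and mitosis genes (-1.08, 5.86e-11) and all 27 oxidative phosphorylation subunits (-0.43, 6.12e-09), each with adjusted p = 0.71 with an estimated correlation. RRM1, which makes nucleotides for DNA synthesis, was at 59.8 ± 10.2 CPM in MI (n = 3) and 106 ± 19 CPM in naive hearts (n = 3), -0.83 (SE 0.21, adjusted p = 0.142), the replication helicase subunit MCM7 at -0.57 (SE 0.26, adjusted p = 0.379), CCNB1 at -1.38 (SE 0.89, adjusted p = 0.547) and MKI67 at -0.1 (SE 0.8, adjusted p = 0.976). EdgeR called 0 genes, with 1905 at an unadjusted p under 0.05 (768 expected by chance) and a smallest adjusted p of 0.076, while DESeq2 called 263 and voom with sample weights 2040.

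MI day 7 replicate 3 stood apart in several lists on day 7. Its G2 and mitosis level was 0.93 log2 CPM, against 4.14 and 4.63 in the other MI libraries and 4.65, 5.22 and 4.69 in naive hearts, and its neutrophil level was 1.12 against -2.07 and -2.66. The neutrophil list (median 3.32, camera adjusted p = 0.0168, and 0.71 with an estimated correlation) and the matrix list (-0.44, 0.00152, and 0.727 with an estimated correlation) lost their calls without it, at 0.42 (0.483) and -0.16 (0.395). Camera also placed the fatty acid (-0.25, 0.0129), Schwann cell (-1.04, 0.00419), erythroid (-1.07, 0.03) and heat shock (-0.28, 0.0167) lists lower, each with adjusted p = 0.71 with an estimated correlation. Of the 9 camera calls on day 7, the 5 for S phase, G2 and mitosis, oxidative phosphorylation, fatty acid and Schwann cell genes held in every alternative of the fit. VEGFA, which drives vessel growth, was at 168 ± 21.2 CPM in MI and 79.5 ± 9.96 CPM in naive hearts (1.08, SE 0.31, adjusted p = 0.177). NPPA was at 2.19 (SE 1.52, adjusted p = 0.588) and COL1A1 at -0.95 (SE 0.79, adjusted p = 0.657). Adjusted over the list alone, 1 S phase gene was lower, and 1 gene was higher in each of the contractile, lymphocyte, smooth muscle, hypoxia, inflammatory and immediate early lists.

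**Figure D3:**
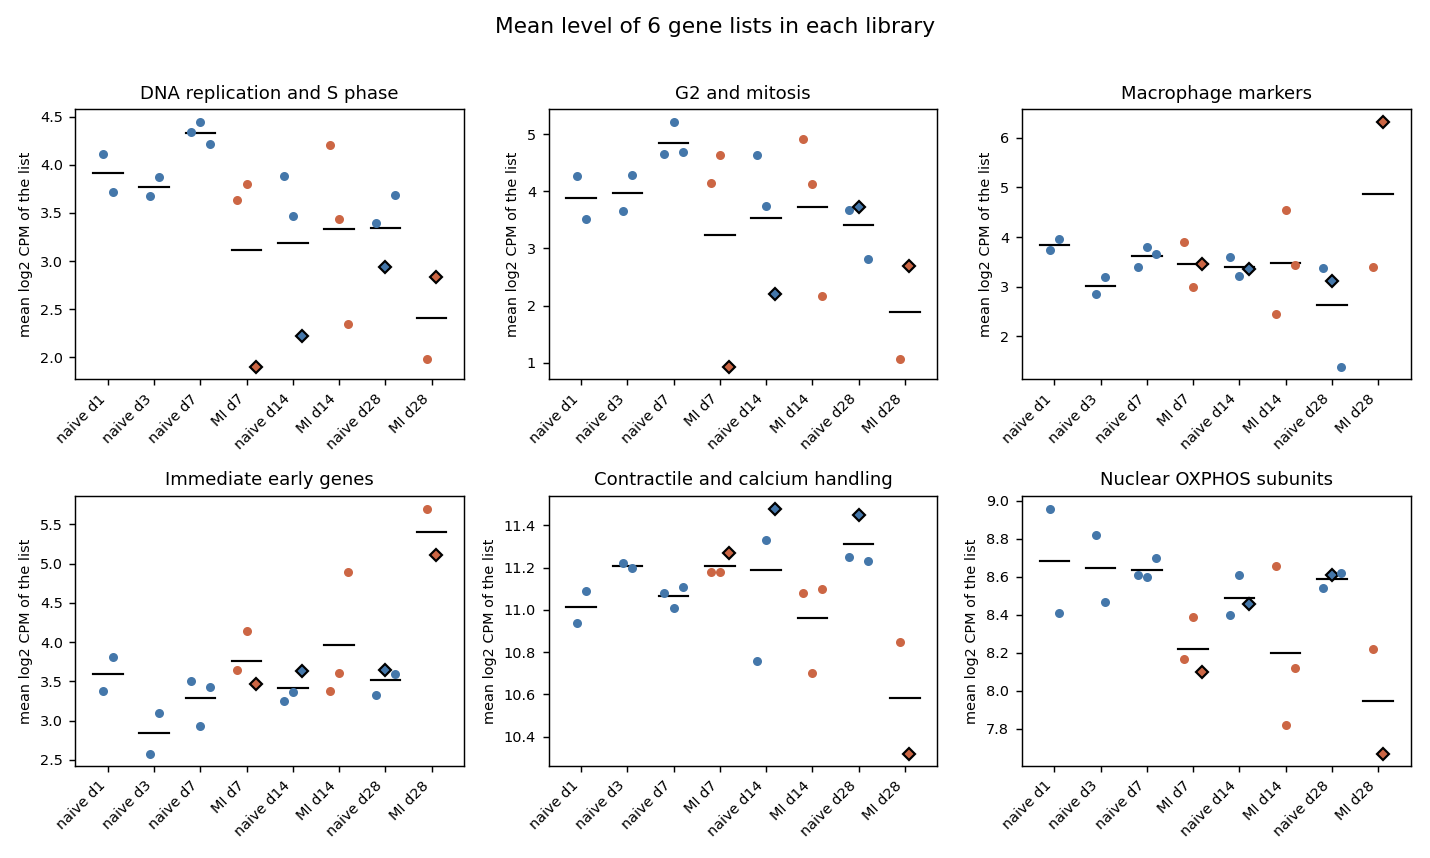
Mean level of 6 gene lists (vertical axes, log2 CPM) in each library (points) of the 8 groups (horizontal axes; naive blue, MI orange, d for postnatal day), with group means as lines and 4 libraries of a second set as outlined diamonds. MI day 7 replicate 3 lies at 0.93 in the G2 and mitosis panel, and MI day 28 replicate 2 at 6.33 in the macrophage panel.

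Compared with naive hearts, MI hearts on day 14 had higher matrix and epicardial lists and lower energy metabolism lists, again with no gene past the test. The comparison asks what remains 2 weeks after birth. Of 32 matrix genes 30 lay higher (median 0.54, camera adjusted p = 9.28e-05), as did all 8 epicardial markers (1.22, 0.000964), and all 27 oxidative phosphorylation subunits (-0.28, 1.79e-06) and 13 mitochondrially encoded genes (-0.45, 0.00432) lay lower, each with adjusted p = 0.489 with an estimated correlation. POSTN was at 215 ± 135 CPM in MI (n = 3) and 59.5 ± 36.8 CPM in naive hearts (n = 3), 1.85 (SE 0.96, adjusted p = 0.974). The atrial and fetal light chain MYL4 was at 2.4 (SE 1.02, adjusted p = 0.911), and MKI67 at 1.25 (SE 0.81, adjusted p = 0.999). EdgeR called 0 genes, with 821 at an unadjusted p under 0.05 and a smallest adjusted p of 0.476, while DESeq2 called 14 and voom with sample weights 0.

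The matrix, epicardial and oxidative phosphorylation positions on day 14 rested on MI day 14 replicate 2. Its epicardial level was 3.95 log2 CPM against 0.34 and 1 in the other MI libraries, and its matrix level 8.01 against 6.61 and 6.34. Without it, the medians were 0.05 for matrix, 0.3 for epicardial markers and -0.1 for oxidative phosphorylation, and these lists were not called. The mitochondrially encoded genes rested on naive day 14 replicate 3, a library of the second set, without which they were at -0.14 (0.558). Of the 14 camera calls on day 14, 0 held in every alternative of the fit. Camera also placed higher the neutrophil (1.62, 0.0156), inflammatory (0.7, 0.0171), fibroblast (0.48, 0.0384), immediate early (0.47, 0.0413) and heat shock (0.16, 0.0478) lists, and lower the fatty acid (-0.34, 3.06e-05), contractile (-0.3, 0.00432), endothelial (-0.34, 0.00808) and Schwann cell (-0.59, 0.0478) lists, each with adjusted p = 0.489 with an estimated correlation. The interferon list lay higher (0.61, 0.0222, and adjusted p = 0.642 with an estimated correlation). Adjusted over the list alone, 3 epicardial markers and 1 fibroblast marker were higher. ANKRD1, a strain-induced nuclear protein, was at -1.23 (SE 0.5, adjusted p = 0.909).

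The effect of MI changed between ages for 2 genes, both named because the count is small and so chosen after their values were seen. This pair of tests asks whether the response to injury depends on the time since it. ENSSSCG00000035617, a gene with no symbol in the sources used here, differed by -3.74 between the MI effects of days 14 and 7 (SE 0.52, adjusted p = 0.0236) and by -4.52 between those of days 28 and 7 (SE 0.57, adjusted p = 0.00767). It was at 48.7 ± 14.5 CPM in MI and 10.7 ± 2.57 CPM in naive hearts on day 7 (n = 3 each), at 14.9 ± 0.752 and 43.6 ± 13.8 CPM on day 14 (n = 3 each), and at 9.95 ± 6.38 (n = 2) and 50.4 ± 7.11 CPM (n = 3) on day 28. ANPEP, a membrane aminopeptidase of myeloid and stromal cells, differed by 5.47 between days 28 and 7 (SE 0.83, adjusted p = 0.0372), at 12.2 ± 1 CPM in MI and 0.632 ± 0.254 CPM in naive hearts on day 28, and at 0.744 ± 0.321 and 1.7 ± 0.913 CPM on day 7. EdgeR called these 1 and 2 genes, with 1086 and 2924 at an unadjusted p under 0.05, DESeq2 33 and 695, and voom with sample weights 5 and 35. In the test of days 14 and 7, the call of ENSSSCG00000035617 held without MI day 7 replicate 2 and without naive day 14 replicate 1, and was lost without any other library, with fold changes between -3.94 and -3.45.

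**Figure D4:**
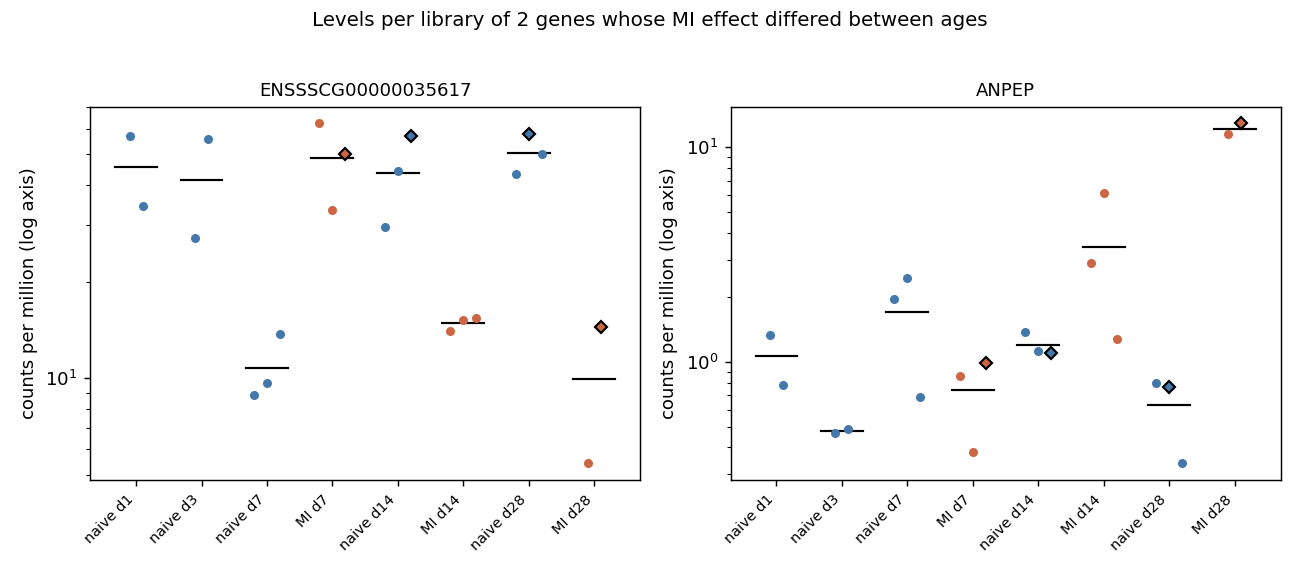
CPM (vertical axes, log scale) of ENSSSCG00000035617 and ANPEP in each library (points) of the 8 groups (horizontal axes; naive blue, MI orange, d for postnatal day), with group means as lines and 4 libraries of a second set as outlined diamonds. Naive day 7 hearts had 10.7 CPM of ENSSSCG00000035617 on average, and MI day 28 hearts 12.2 CPM of ANPEP.

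Several lists also differed in MI effect between ages, given as the median difference, the camera adjusted p, the adjusted p with an estimated correlation and, where not 0, the calls adjusted over the list alone; the same order is kept for the naive ages. From day 7 to day 14, the effect was more positive for all 27 S phase genes (median 1.25, camera adjusted p = 4.72e-11, and 0.616 with an estimated correlation), all 33 G2 and mitosis genes (1.32, 2.01e-10, 0.688) and the matrix (0.95, 3.11e-08, 0.688), epicardial (1.63, 0.000276, 0.616; 3), heat shock (0.4, 0.000589, 0.616) and fibroblast lists (0.8, 0.0428, 0.877). It was more negative for the contractile list (-0.25, 0.0193, 0.688; 1) and YAP and TEAD targets (-0.33, 0.0428, 0.688). From day 7 to day 28, it was more positive for all 21 macrophage markers (2.89, 7.87e-08, 0.486; 17 adjusted over the list alone) and for the inflammatory (2.53, 4.82e-07, 0.37; 10), matrix (1.64, 4.35e-05, 0.725; 4), lymphocyte (2.47, 5.24e-05, 0.719; 4), epicardial (1.7, 0.00271, 0.486; 4), adipocyte (4.31, 0.00271, 0.486; 4), immediate early (1.52, 0.00284, 0.37; 1) and Schwann cell lists (2.44, 0.0489, 0.719). It was more negative for the contractile (-0.97, 2.13e-06, 0.37; 1), fatty acid (-0.45, 0.019, 0.725) and growth regulator lists (-0.43, 0.0489, 0.486). Without MI day 28 replicate 2 the matrix and lymphocyte medians of this last test turned to -0.08 and -0.12. The macrophage level on day 28 was 3.39 log2 CPM in MI replicate 1 and 6.33 in replicate 2, against 3.38, 3.11 and 1.38 in naive hearts. The adipocyte level was 4.91 in MI replicate 1 and -0.62 in replicate 2, against -0.6, -1.32 and -1. Most of the macrophage difference thus lay in replicate 2, and that of the adipocyte list in replicate 1. Without the 4 libraries of the second set the G2 and mitosis difference of days 14 and 7 was 0.45 (camera adjusted p = 0.79). Held in every alternative of the fit were the calls of S phase, matrix, epicardial and heat shock genes for day 14 (4 of 8). For day 28, those of macrophage and inflammatory genes held (2 of 11). Matrix levels on day 14 were 6.61, 8.01 and 6.34 log2 CPM in MI and 6.92, 6.42 and 5.5 in naive hearts. On day 7 they were 7.06, 6.16 and 5 in MI and 6.76, 6.43 and 6.57 in naive hearts. The matrix difference thus rested largely on MI day 14 replicate 2 and MI day 7 replicate 3, and no alternative left out both. In the epicardial list MI day 14 replicate 2 was at 3.95, against 0.34 and 1 in the other MI libraries. S phase levels were 4.21, 3.44 and 2.34 log2 CPM in MI and 3.88, 3.47 and 2.22 in naive hearts on day 14. On day 7 they were 3.63, 3.8 and 1.9 in MI and 4.34, 4.45 and 4.22 in naive hearts. The S phase difference thus rests in part on the high naive day 7 libraries, which other comparisons share.

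In naive hearts, the fatty acid list lay higher and the matrix, endothelial and smooth muscle lists lower on days 3 and 7 than on day 1. The interferon list lay lower on day 3, and none of these was called with an estimated correlation. These comparisons ask how the uninjured heart changes with age, and both share the naive day 1 libraries, so they are not independent. On day 3 against day 1 (n = 2 each), all 18 interferon genes lay lower (median -1.65, camera adjusted p = 1.39e-10, and 0.473 with an estimated correlation), as did all 32 matrix genes (-0.7, 6.16e-06, 0.676) and all 13 endothelial markers (-0.61, 6.05e-06, 0.473), while 23 of 25 fatty acid genes lay higher (0.47, 1.61e-05, 0.473). HADHA, a subunit of the enzyme complex that shortens long fatty acids, was at 1.43e+03 ± 76.2 CPM on day 3 and 853 ± 155 CPM on day 1 (0.74, SE 0.35, adjusted p = 0.965), and VWF, which tethers platelets, at -1.3 (SE 0.41, adjusted p = 0.965). Lower too were the inflammatory (-0.65, 0.000224, 0.473), smooth muscle (-0.52, 0.000379, 0.394), macrophage (-0.94, 0.000436, 0.676), immediate early (-0.63, 0.00106, 0.394; 1) and fibroblast lists (-0.73, 0.00202, 0.643). EdgeR called 0 genes, with 543 at an unadjusted p under 0.05, DESeq2 3 and voom with sample weights 0. Without naive day 1 replicate 2, the matrix list was at -0.34 (0.144), the macrophage list at -0.72 (0.0723) and the fatty acid list at 0.17 (0.0792), and the fibroblast and immediate early lists were also lost. Of 9 calls, those of the interferon, inflammatory and smooth muscle lists held in every alternative of the fit.

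On day 7 against day 1, 32 of 33 G2 and mitosis genes lay higher in naive hearts (1.03, 2.54e-05, 0.956), as did 22 of 25 fatty acid genes (0.39, 2.54e-05, 0.954), S phase genes (0.35, 0.000919, 0.956) and imprinted genes (0.27, 0.0196, 0.184; 1 adjusted over the list alone). Lower were the smooth muscle (-0.52, 0.000245, 0.184; 1), endothelial (-0.41, 0.00133, 0.956), matrix (-0.54, 0.0035, 0.956) and fibroblast lists (-0.58, 0.0196, 0.956). RRM1 was at 106 ± 19 CPM on day 7 (n = 3) and 60.2 ± 0.466 CPM on day 1 (n = 2), 0.82 (SE 0.24, adjusted p = 0.853), and CCNB1 at 1.78 (SE 1.04, adjusted p = 0.922). EdgeR called 0 genes, with 835 at an unadjusted p under 0.05, DESeq2 12 and voom with sample weights 0. Without naive day 1 replicate 2, the G2 and mitosis list was at 0.63 (0.0762), the S phase list at 0.12 and the fatty acid list at 0.3 (0.179), none of them called, and of 8 calls that of the smooth muscle list alone held in every alternative of the fit.

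After the first week, the cell cycle lists of naive hearts lay lower. On day 14 against day 7 (n = 3 each), 26 of 27 S phase genes were lower (-1.01, 7.64e-14, 0.727; 1 adjusted over the list alone), and all 33 G2 and mitosis genes (-1.08, 4.08e-10, 0.929). On day 28 against day 7 (n = 3 each), all 27 and all 33 were lower (-0.97, 2.27e-12, 0.897; 3, and -1.45, 1.06e-11, 0.897). On day 14, replicate 3, of the second set, was lowest in S phase and in G2 and mitosis, at 2.22 and 2.2 log2 CPM. The other day 14 libraries were at 3.88 and 3.47 for S phase and at 4.63 and 3.75 for G2 and mitosis. RRM1 was at 58.5 ± 10.5 CPM on day 14 and 65.3 ± 8.44 CPM on day 28, against 106 ± 19 CPM on day 7 (-0.86, SE 0.21, adjusted p = 0.242, and -0.7, SE 0.21, adjusted p = 0.429). TOP2A, which untangles chromosomes, was at -1.19 (SE 0.83, adjusted p = 0.715) and CCNB1 on day 28 at -1.67 (SE 0.9, adjusted p = 0.734). EdgeR called 0 genes in either, with 1357 and 1103 at an unadjusted p under 0.05, DESeq2 96 and 57, and voom with sample weights 918 and 433. Both comparisons use the same naive day 7 libraries. So do naive day 7 against day 1, MI against naive hearts on day 7, and both changes in MI effect. These libraries had the highest S phase levels of all groups (4.34, 4.45 and 4.22 log2 CPM), so these results share their chance values.

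Interferon and immune lists of naive hearts were also lower on day 28 than on day 7. All 18 interferon genes (-1.16, 6.89e-08, 0.897) and all 21 macrophage markers (-0.8, 2.65e-06, 0.897) lay lower, with the matrix (-0.49, 0.00133, 0.897) and lymphocyte lists (-0.73, 0.0206, 0.897), and 21 of 22 contractile genes lay higher (0.26, 0.0206, 0.897; 1). The complement subunit C1QB on day 28 was at -0.96 (SE 0.67, adjusted p = 0.812). On day 14 the interferon (-0.83, 0.00758, 0.929), epicardial (-1.58, 0.0208, 0.929) and oxidative phosphorylation lists (-0.12, 0.0228, 0.929) were lower, and the smooth muscle list (0.36, 0.0228, 0.727) and YAP and TEAD targets (0.31, 0.0299, 0.929; 1) higher. Without naive day 28 replicate 3, the macrophage list was at -0.47 (0.0722) and the lymphocyte list at -0.27. Without naive day 7 replicate 3, the interferon list on day 14 was at 0.05 (0.926). That library was at 6.25 log2 CPM in this list, against 4.32 and 3.82 in the other naive day 7 libraries. Naive day 28 hearts were at 4.19, 4 and 2.33, so the day 28 difference also rested in part on that library. The S phase and mitosis calls held in every alternative of the fit for both ages, and so did those of the interferon and matrix lists for day 28, but no other.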

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

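Chosen only after the result was seen were the tests of the second library set, of the cardiomyocyte share, of age for the small RNA features, and of single libraries for the cell cycle lists, while the tests of sequencing depth, of 1 MI library alone and of other splits of the samples were set before their result was seen.

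The effect of MI differed between ages for ENSSSCG00000035617, by -3.74 from day 7 to day 14 (SE 0.52, edgeR adjusted p = 0.0236; over its alternatives 2.79e-08 to 0.18) and by -4.52 from day 7 to day 28 (SE 0.57, adjusted p = 0.00767; 1.95e-11 to 0.0471). It differed for ANPEP by 5.47 from day 7 to day 28 (SE 0.83, adjusted p = 0.0372; 9.3e-08 to 0.134). Each was found by an interaction test over 15359 genes. ANPEP was higher in both MI libraries than in each of the 3 naive libraries on day 28. For the change from day 7 to day 14, 2 of 40 drawn splits (of 200 possible) called at least as many genes as the real 1, so chance was not excluded. The other split, which exchanges MI day 14 replicate 3 with naive day 14 replicate 1, called 35 genes, and the reason was not tested.

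The day 7 part of the first change comes from naive day 7 hearts, where ENSSSCG00000035617 was at 10.7 CPM against 45.7 CPM on day 1, and these libraries were also the lowest in 182 small RNA features (mean log2 CPM -2.51 to -2.4, against -2.2 to -1.23 in the other 18). The features were at a median of 0.74 in MI against naive hearts on day 7, so MI hearts of the same age were not as low. The naive libraries had been picked as the lowest of all, which set the direction of this value in advance. It cannot decide about age, because a change with age in naive hearts alone would look the same. After thinning all libraries to the lowest total the median was 0.67 over the 135 features still kept (0.8 for these before thinning), above the bound of a depth effect set beforehand. The gene was about as low in MI hearts on days 14 and 28 (5.44 to 15.4 CPM), where the small RNA features were not (-2.02 to -1.23), so a low level of the gene does not need low small RNA features. A preparation difference of the naive day 7 libraries was not tested, because no other naive day 7 library exists, and it stays open with a difference of the group.

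The 1053 genes called in MI against naive hearts on day 28 could come from the second library set, from a lower share of cardiomyocytes or from 1 of the 2 MI libraries alone. With a term for the second set 646 genes were called, 603 of them among the 1053, which argues against that set as the whole cause. A lower share of cardiomyocytes raises markers of all other cells alike only if those cells keep their proportions to each other. Those proportions were not measured, so the test of macrophage over endothelial markers cannot decide. These markers differed by 1.89 log2 CPM between MI and naive libraries, with an SE over libraries of 1.95. They lay at 3.7 and -0.08 from the naive mean in MI replicate 2, and both at 0.77 in replicate 1. A lower share of cardiomyocytes stays open. Of the genes called without MI replicate 1, 56.7% lay on the same side in that replicate against naive day 14 hearts, under the bound set beforehand for the explanation, and of those called without replicate 2 71.8% did, between the bounds. So a part resting on 1 MI library, and injury itself, stay open too, and with 2 MI libraries no split of the samples was counted.

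Cell cycle lists lay lower in MI than in naive hearts on day 7, where edgeR called 0 genes (1905 at an unadjusted p under 0.05, 263 calls by DESeq2). A single library, MI day 7 replicate 3, is not the whole cause for the S phase list, since the other 2 MI libraries lay -0.62 log2 CPM (SE 0.11) from the naive ones. For the G2 and mitosis list they lay -0.46 (SE 0.3) from them, which leaves that explanation open. The second library set, which holds this replicate, is open for the G2 and mitosis list: 1 of its 3 other libraries, naive day 14 replicate 3, lay below the rest of its group (by -1.99, against 0.49 and 1.64 for the others). Injury, and the naive day 7 libraries as a high reference, stay open as well.

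For the comparisons of 3 against 3 pigs, 10 splits exist, too few for a share under 0.05. In MI against naive hearts on days 7 and 14, and in naive hearts on day 14 and on day 28 against day 7, the real split called 0 genes and the highest other split 0, so all 10 splits called as many.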

How the results depend on the processing

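Chosen only after the result was seen were the term for the second library set and the fit without its 4 libraries; the other settings were chosen before the data were examined. No paired analysis was possible because the labels give pig numbers but no number, litter or day that groups share.

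The count of 1053 genes in MI against naive hearts on day 28 stayed within 1.5 times under DESeq2 size factors (1120, with 74.1% higher against 65.2%), without a count filter (721), without haemoglobin and mitochondrial genes (1119) and without the 4 libraries (1000, of which 334 were among the 1053). The share called higher was 89% without MI replicate 1, 95.7% with voom and 55% without the 4 libraries. The count moved to 2205 with DESeq2's Wald test, 46 with voom and sample weights, 2 in a fit to the compared groups and 646 with the set term. The fit to 5 libraries has fewer samples to estimate the spread. For the change to day 28, however, the fit to the compared groups raised the calls from 2 to 135. The fit of all 21 libraries shares 1 spread per gene over the 8 groups. The MI day 28 pair differed more than any other same-group pair (r 0.913, chi-square per degree of freedom 964). Its voom weights were 0.32 each, so the 1053 calls may rest on a spread too small for that group. This was not tested, nor was the cause of the other moves.

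DESeq2's Wald test moved the counts of every comparison: to 263 in MI against naive hearts on day 7, 14 on day 14, 33 and 695 for the changes in MI effect from day 7 to days 14 and 28, and 3, 12, 96 and 57 for the naive comparisons of day 3 with 1, 7 with 1, 14 with 7 and 28 with 7. On simulated data it made more false calls than edgeR in every comparison. Voom with sample weights gave 2040 in MI against naive hearts on day 7, 5 and 35 for the changes in MI effect, and 918 and 433 for naive days 14 and 28 against 7, and it gave MI day 28 replicates 1 and 2 and MI day 7 replicate 3 weights of 0.32, 0.32 and 0.36. The fit to the compared groups gave 135 for the change to day 28 and 4 for naive day 28 against 7. With the set term, the changes in MI effect gave 0 and 1 genes, and without the 4 libraries the change to day 28 gave 367 and MI against naive hearts on day 14 gave 2. Without those libraries the change to day 14 gave 1 gene, but not the same gene. The cause was not tested.

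Leaving out 1 library at a time gave 0 to 0 genes in MI against naive hearts on day 7, 0 to 1 on day 14 (1 without MI day 14 replicate 1) and 17 to 1162 on day 28. It gave 0 to 1 for the change to day 14 and 1 to 528 for the change to day 28, with 528 without MI day 28 replicate 1, 179 without replicate 2, 13 without naive day 28 replicate 1 and 10 without MI day 7 replicate 3. For the naive comparisons it gave 0 to 0 (day 3 against 1), 0 to 1 (day 7 against 1, 1 without naive day 1 replicate 1), 0 to 0 (day 14 against 7) and 0 to 0 (day 28 against 7). Leaving out a library of a group of 2 leaves 1, which is then assumed to vary like the other groups.

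Of the values of named genes under the alternatives, 8215 stayed the same. These were called in the same direction, or uncalled in both fits and within 1 SE of the reported log2 fold change. Another 321, uncalled in both fits, moved by more than that SE. Of the rest, 473 lost the call, 45 gained one, and 5 reversed. All 5 were in MI against naive hearts on day 28: ADIPOQ at -0.02 without MI day 28 replicate 1, JCHAIN at -0.03 and CD4 at -0.93 without MI day 28 replicate 2 (4.65 and 4.38 without replicate 1), and JCHAIN at -0.05 and CD4 at -1 without the 4 libraries, which include that replicate. Their levels were high in 1 MI library, as given with their values. Of 69 called genes that the naming rules pick on day 28, 67 stayed called with DESeq2 size factors, 65 with the Wald test (4 had no adjusted p there), 52 without the filter, 68 without haemoglobin and mitochondrial genes, 46 with the set term, 27 without the 4 libraries, 5 with voom and 1, CXCL2, in the fit to the compared groups.

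For lists, the number of called members was equal or within 1.5 times of the reported one in 3690 cases, and differed by more in 300. Lists with 0 calls in both fits count as equal. The list medians were not compared in this way. The camera calls of the inflammatory, immediate early, fatty acid and nuclear oxidative phosphorylation lists on day 28 held in all alternatives of the fit, and 0 list calls held with an estimated correlation in any comparison. Pseudocount alternatives were not run because the values are counts.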

Other observations

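All tests in this part were chosen only after the result was seen.

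Gene families outside the planned lists also held called genes in MI hearts on day 28, in the comparison with the most calls. Of 19 complement genes, 12 were called higher (median log2 fold change 3.25, camera adjusted p over 7 families 7.22e-10, and 0.27 with an estimated correlation), among them C1R, C1S, C2, CFB and the inhibitor SERPING1, beside C3 and C4A. Of 12 cathepsins, the lysosomal proteases, all were fitted higher and CTSB, CTSH, CTSL and CTSS were called (median 0.9, 0.001, and 0.27 with an estimated correlation, fry 0.0178; CTSS is also in the macrophage list). The 5 tested MHC class II genes, which present antigens, were all fitted higher with 0 calls (1.68, 0.00238, and 0.286 with an estimated correlation, fry 0.0443). Complement genes may have risen as a group, but fry (adjusted p = 0.00977) and camera with an estimated correlation (0.27) part here, and the complement list shares C1QA, C1QB, C1QC and C7 with the marker lists, so this stays a hypothesis. MI replicate 2, which has the high macrophage markers, carries most of this: without it the medians were 2.06 for complement, 0.06 for cathepsins and 0.49 for MHC class II, against 4.05, 1.31 and 2.34 without replicate 1. All 7 families were picked after the calls were seen.

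Ribosomal protein genes of the mitochondrion were mostly fitted lower and those of the cytosol higher, and the difference between the families was not tested. Of 67 mitochondrial ribosomal protein genes, 55 were fitted lower and 7 were called, all lower: MRPL4, MRPL21, MRPL47, MRPS9, MRPS28, MRPS30 and MRPS31 (median -0.43, -0.59 without MI replicate 1 and -0.23 without replicate 2, camera adjusted p = 3.68e-09, and 0.286 with an estimated correlation, fry adjusted p = 0.0178). Of 62 cytosolic ribosomal protein genes, 58 were fitted higher with RPL10, RPS2, RPS14 and RPS20 among those called (median 0.66, 0.18 without MI replicate 1 and 1.05 without replicate 2, 2.7e-11, and 0.286 with an estimated correlation, fry 0.0443). The lower position of nuclear genes for mitochondrial respiration may extend to the mitochondrial ribosome, but camera with an estimated correlation (0.286) did not call the family while fry did, so this stays open. Proteasome subunits (median -0.21, 0 of 36 called, 0.0164, and 0.498 with an estimated correlation) and mitochondrial carriers (-0.15, 2 higher and 4 lower of 38, 0.26) had smaller medians, whose sign rested on 1 MI library (-0.59 and -0.43 without replicate 1, 0.1 and 0.06 without replicate 2).

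Across the whole profile, libraries were closest to libraries of the same injury status. The nearest library by Pearson correlation over all tested genes had the same status for 21 of 21 libraries (19 by Spearman correlation), against a mean of 10.9 over the 4000 permutations of status within age. Of these, 2 gave 21, the real one included, and the rest at most 19, an exact permutation p of 0.0005, one-sided. The nearest library was in the same group, of the same age too, for 5 of 21, against 1.8 over 100000 permutations (permutation p = 0.0599, one-sided). For the second library set, 2 of the 4 libraries had their nearest library in the set. MI and naive libraries may therefore differ across the profile over all ages, and no single age was tested. A preparation of MI and naive libraries apart from each other would give the same and was not tested, because the labels give no batch. Pig numbers in the titles were consecutive or nearly so within most groups. MI pigs of days 7 and 14 had higher numbers than every naive pig, while those of day 28 did not. A litter or cohort that goes with injury status could thus also give the same. The permutation treats pigs of an age as exchangeable and cannot separate this from injury, and the labels give no litter.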
